A study of Arabidopsis thaliana with 12 samples.

How the data were processed

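Expression was measured on Affymetrix ATH1 arrays in inflorescence tips of Arabidopsis thaliana. Per the series design, the plants were ap1-1 cal-1 double mutants, homozygous at both genes, and carried a 35S-driven fusion of AGAMOUS, the floral homeotic MADS-domain protein, to the rat glucocorticoid receptor. Steroid treatment of such plants starts stamen and carpel development synchronously. Per the labels' protocols, plants grew at 18 °C with 16 h of light and 8 h of dark. Dexamethasone at 10 µM in 0.015% Silwet L-77, from a 10 mM stock in ethanol, was applied to the tips, and the mock solution held the same Silwet and 0.1% ethanol. RNA was taken from the apices 1, 3 or 7 days later and stored for 2 weeks, and biotinylated cRNA was made from 6 µg of total RNA. Per the series design, each of the 6 groups (mock or steroid on each day) has 2 independent samples, and each sample was hybridised to 1 array, giving 12 arrays.

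The deposited table holds one signal intensity per probe set and array on a linear scale, and the submitters' processing notes name MAS5 as the tool without a version, target or scaling. Besides 64 array controls the table holds 22746 probe sets, and 5 of its values are 0. The deposited array medians ran from 16.1 to 95.2, so the arrays shared no common scale. Each array was therefore multiplied to a common median of 24.8. An offset of 4.35, the median over arrays of each array's 20th percentile, was added before taking log2. Fold changes below are on this offset scale, so they understate ratios of weak signals. Group means and SDs are of the scaled signal without the offset. A probe set was tested if it was no control and at least 2 of the 12 arrays exceeded that array's own 40th percentile, which left 16511. The file of gene names gives a single symbol to 13513 probe sets and several to 503, and leaves 8730 that are not controls without one. Of those with a single symbol, 13436 were matched to the annotation by gene identifier, and where the annotation has no symbol the locus is used as the name. Among the tested probe sets, 9232 had a single name and 7279 did not. A probe set without a name is given by its identifier.

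All 12 arrays entered one linear model with 6 group means and 6 residual degrees of freedom, fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend, 6.89 prior degrees of freedom). The 8 contrasts were steroid minus mock on each day, the mean of these 3 differences, the 3 differences between them, and mock day 7 minus mock day 1. Tests were two-sided, with Benjamini-Hochberg adjustment over the 16511 probe sets per contrast and a threshold of 0.05, and a probe set past it is called. An exact permutation test of 2 arrays against 2 cannot give a p below 0.333, so no single gene was tested that way. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists within a contrast, and again with an estimated correlation and with limma's fry. A set test needed at least 5 tested members.

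The contrasts, filter, offset, gene lists, naming rule and the alternatives not marked below as added were fixed before the data were examined. The naming rule took, for each daily contrast and for the 3 days together, up to 8 higher and 8 lower named probe sets with the largest fitted change among those called. In these every steroid array lay beyond every mock array of that day, or, over the 3 days, the mean difference had one sign on each day. It also took up to 4 called members of each list, or up to 2 members with values only where none was called. The rule put AGAMOUS and 9 other floral organ identity genes first, but the gene-name file names none of these 10. No value is therefore given under their names, and treatment could not be checked through AGAMOUS by name. Probe sets given by identifier below may include these genes. Counts of called list members likewise cover only members with a name.

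Several choices were made after the data were seen. Of the 208 members of the 14 lists fixed beforehand, 26 were named on the array and 17 were tested, so none of these lists reached the size for a set test. Instead, 19 lists built from the names on the array took the set tests. None of the lists fixed beforehand had more than 3 tested members, so adjustment over the list alone differs little from no adjustment. The fit of the 4 day 7 arrays alone, with 2 residual degrees of freedom, was an alternative fixed beforehand. Reporting it at length and repeating the naming rule on it were chosen later, because the spread of those arrays was far below that of days 1 and 3. Further additions were array quality weights per group, the deposited values without scaling, a block for replicate number shared by days 1 and 3, and a comparison of the arrays numbered 1 with those numbered 2.

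The alternatives fixed beforehand were quantile normalization, centring over the tested probe sets, an offset halved to 2.17 or doubled to 8.70, a floor in place of the offset, no filter, a filter at the 60th percentile, no variance trend or a robust one, a replicate block, the scan date as a block, fits on the arrays compared alone, and leaving out each array in turn. The scan dates in the experiment files are given as scan 1 to scan 5. The code was tested on simulated data: on arrays drawn with the spread measured on each day, 200 of the 16511 probe sets per day were shifted by 1 or 2 log2 units, besides a smaller shift of 1 list. Fitted on 12 arrays, day 1 gave 154 calls of which 45 were false, day 3 gave 138 with 29 false, and day 7 gave 86 with 0 false. Fitted on the 4 arrays of the day, they gave 75 calls with 1 false, 87 with 7 false and 216 with 11 false. The array number limits the precision of every value here.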

Results

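Signals of 22746 probe sets besides 64 array controls were read in inflorescence tips of the ap1-1 cal-1 plants carrying the AGAMOUS fusion, with 2 mock and 2 steroid-treated samples on each of days 1, 3 and 7. The day 7 arrays were brighter, with deposited medians from 62.6 to 95.2, against 16.1 to 20.8 on day 1 and 20.1 to 32.2 on day 3. Their replicates were also closer. Pearson's r across tested probe sets, which are not independent replicates, was 0.985 for mock and 0.982 for steroid on day 7, and ran from 0.887 to 0.916 in the other 4 groups. The median residual SD of log2 signal was 0.335 on day 1, 0.321 on day 3 and 0.132 on day 7. The ratio of 3' to 5' GAPDH signal, a sign of RNA or cRNA quality, averaged 7.70 ± 5.01 (SD, n = 2) in mock and 8.20 ± 0.380 in steroid on day 1. On day 3 it was 10.3 ± 2.69 and 11.2 ± 6.50, and on day 7 it was 1.31 ± 0.00245 and 1.25 ± 0.226. The ubiquitin ratio separated the days likewise, at 6.22 in mock and 5.46 in steroid on day 1, 5.75 and 4.77 on day 3, and 1.64 and 1.85 on day 7. The actin ratio did not, at 7.10 in mock and 5.13 in steroid on day 1, 7.10 and 4.0 on day 3, and 5.20 and 6.23 on day 7.

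The day 1 comparison asked which transcripts differed between steroid and mock tips a day after the treatment meant to activate AGAMOUS. No group without the fusion was treated, so effects of the steroid itself cannot be told apart from those of AGAMOUS on any day. The gene AT3G11000 rose from a scaled signal of 28.8 ± 2.62 (SD, n = 2) in mock to 102 ± 6.71 in steroid tips, a 3.23-fold change (log2 1.69, SE 0.22, limma adjusted p = 0.0400), with both steroid arrays above both mock arrays. Probe sets 260355_at and 263333_at, which have no gene name in the table, also rose, from 2.25 to 57.5 and from 1.14 to 22.2 (log2 3.22 and 2.27, both adjusted p = 0.0400). The difference in 263333_at was not called later, at log2 0.59 on day 3 and -0.10 on day 7. These 3 were the calls of limma among 16511 probe sets, all higher. An unadjusted p under 0.05 was found for 1374, against 826 by chance, but this excess is not evidence of steroid effects. The spread shared by 12 arrays lies below that of day 1, so the p-values of this fit tend to be too small here. On simulated arrays 45 of its 154 day 1 calls were false. None of the 17 tested members of the lists fixed beforehand was called, 1 had an unadjusted p under 0.05, and 1 passed when adjusted over the list alone: the stamen regulator ROXY1, a glutaredoxin, at log2 -1.22. Its list had only 2 tested members, so this adjustment adds little to the unadjusted p. Fitted on the 4 day 1 arrays, limma called 0 probe sets (517 with an unadjusted p under 0.05). With the scan date as a block it also called 0, and AT3G11000 then had log2 1.77 and adjusted p = 0.0702, the log2 value being the one within scan 5. Leaving out 1 array changed the day 1 calls widely, as given further below. None of the 3 stayed called without mock replicate 1 or either steroid replicate of day 1. The same held without any 1 of the 4 day 7 arrays, and only 263333_at stayed without day 3 steroid replicate 1. Over all alternatives the log2 of AT3G11000 ran from 1.57 to 1.83. That of 260355_at ran from 2.59 to 3.75 and that of 263333_at from 1.65 to 2.89.

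The day 3 comparison asked the same after 3 days. AT3G11000 was again higher, at 136 ± 7.25 in steroid against 35.0 ± 7.90 in mock tips (3.61-fold, log2 1.85, SE 0.22, adjusted p = 0.0144). Probe set 260355_at was 12.2-fold higher, and the unnamed 251898_at rose from 2.05 ± 0.921 to 67.4 ± 43.9 (log2 3.61 and 3.35, both adjusted p = 0.0144). AT3G11000 and 260355_at were thus called on both days, and on day 7 as well. Among the few stamen and carpel genes that had a name and were tested, none passed the threshold. EMS1, a receptor kinase needed for the tapetum, had log2 0.49, and the carpel regulator SPT had -0.21. Most members of those lists had no name here, so the unnamed calls may include such genes. limma called AT3G11000, 260355_at and 251898_at and no other, with 1007 at an unadjusted p under 0.05 against 826 by chance. As on day 1, the p-values of the 12-array fit tend to be too small, with 29 of 138 simulated calls false. Of the 17 tested members of the lists fixed beforehand limma called 0, with 0 under an unadjusted p of 0.05 and 0 adjusted over the list alone. Fitted on the 4 day 3 arrays it called 0 (469), and with the scan date as a block, as within scan 4, it called 251898_at alone, at log2 4.01. The count was 0 without mock replicate 2 or either day 7 steroid replicate, 1 without steroid replicate 2, and 11 without steroid replicate 1, of which 10 were lower.

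On day 7 the gene and the probe set called on both earlier days were again higher, and further genes passed the test. AT3G11000 was 5.65-fold higher (18.2 ± 1.39 in mock, 123 ± 9.74 in steroid, log2 2.50, SE 0.22, adjusted p = 0.000339). AT3G19550 was 5.60-fold higher (19.1 ± 2.36 to 129 ± 32.6, adjusted p = 0.0312), and AT5G57720 5.05-fold (8.83 ± 2.44 to 61.9 ± 6.77, adjusted p = 0.0326). AT2G35310, listed with the synonym REM23 of the REM group of B3-domain transcription factors expressed in reproductive meristems, was 2.81-fold higher (44.6 ± 5.80 to 133 ± 18.5, adjusted p = 0.0328). Among probe sets without a gene name, 260355_at was 83.8-fold higher (log2 6.39), 251898_at 25.3-fold, 254391_at 8.85-fold and 246072_at 5.02-fold, while 246137_at was the only one lower, at log2 -1.70. limma called these 9, with 229 at an unadjusted p under 0.05, far below the 826 by chance, since the spread shared by 12 arrays exceeds that of day 7. A fit of the 4 day 7 arrays gave 2386. The calls of AT3G11000, 260355_at and 251898_at were kept under all 26 alternatives each, whereas those of AT3G19550, AT5G57720 and AT2G35310 were lost without any 1 of the 4 day 7 arrays, and the latter 2 also without any 1 steroid array of days 1 and 3. The count was then 4, 4, 3 and 4 without mock replicate 1, mock replicate 2, steroid replicate 1 and steroid replicate 2. The mock day 7 arrays were read in scan 1 and the steroid day 7 arrays in scan 2, so scan and treatment cannot be told apart on this day.

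**Figure D1:**
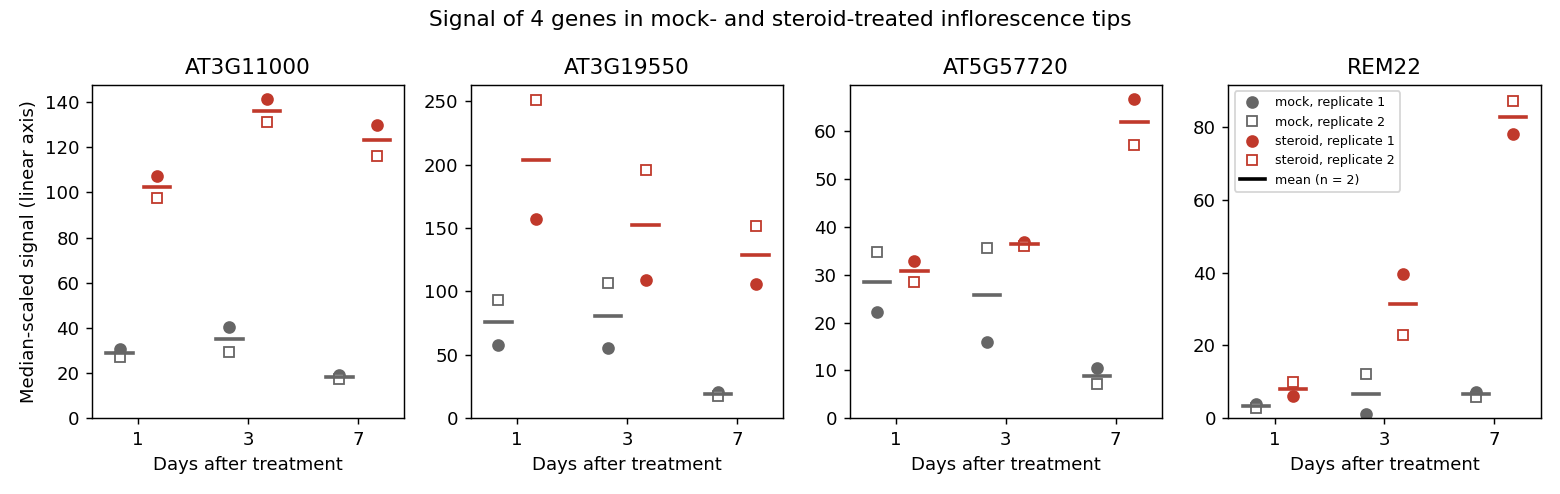
Scaled signal of AT3G11000, AT3G19550, AT5G57720 and REM22 in each of the 12 arrays, by day and treatment, on a linear axis, with the mean of the 2 replicates per group. On day 7 the mean of AT3G11000 was 18.2 in mock and 123 in steroid tips, and that of REM22 was 6.65 and 82.7.

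A fit of the 4 day 7 arrays alone, chosen for naming genes after their small spread was seen, called 267 probe sets, of which 154 were higher, 113 lower and 67 changed at least 2-fold. Named genes made up 61 of the higher and 54 of the lower calls. REM22, another REM gene, was 7.91-fold higher (6.65 ± 0.972 to 82.7 ± 6.42, adjusted p = 2.7e-06 in this fit). AT1G47610 was 6.39-fold higher, AT1G02190 5.03-fold, AT4G26280 4.33-fold and AT5G47600 4.23-fold, beside AT3G11000, AT3G19550 and AT5G57720 as above. The 8 named genes with the largest falls changed less: AT4G37220 by log2 -1.27, AT3G13130 -1.11, AT1G67865 -1.09, AT3G11930 -1.06, the sucrose transporter gene SWEET11 -1.02, AT3G25640 -0.99, AT4G25780 -0.96 and AT4G14020 -0.87. Array weights per group, added after the data were seen, called 289. In the 12-array fit none of the genes newly named here was called on day 7, with adjusted p from 0.0740 for REM22 upward.

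**Figure D2:**
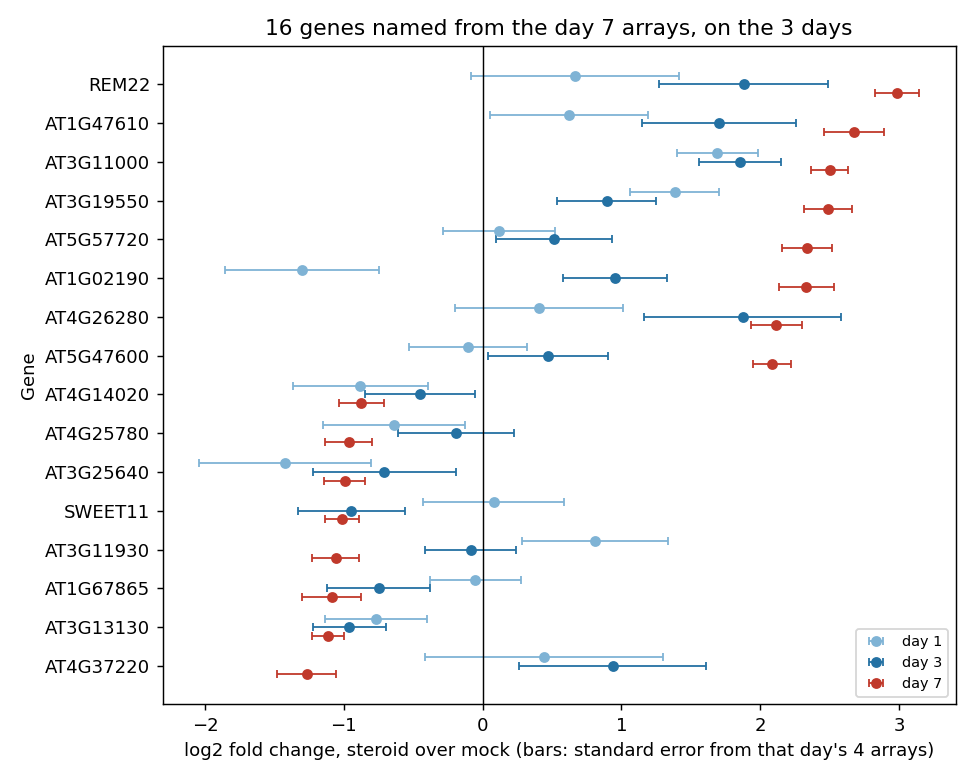
Log2 change of steroid against mock on days 1, 3 and 7 for the 8 higher and 8 lower named genes of the day 7 fit, with bars of 1 SE from the 4 arrays of that day. REM22 stood at 0.67, 1.88 and 2.98 on the 3 days, and SWEET11 at 0.08, -0.95 and -1.02.

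Gene families were then described for day 7 from the same 4 arrays. Of the 5 REM genes tested, 3 were called higher (REM22, AT2G35310 at log2 1.49 and AT2G16210, with the synonym REM24, at 1.27), and all 5 lay above 0. Of 13 SWEET sugar transporters, SWEET10 (log2 1.54, 2.91-fold) and SWEET1 (0.73) were higher and SWEET11 was lower. Among the 22 tested of 30 floral regulators named on the array, NUB, a zinc finger gene of stamen and carpel growth, was higher (log2 1.80, 3.49-fold). The other tested members did not pass. Single members of further families were higher: GH3.3 of auxin conjugation (1.09), the actin gene ACT11 (0.82), the Aurora kinase gene AUR1 (0.53), the chalcone isomerase-like gene CHIL (0.65), the wall acetylation family gene TBL26 (0.82) and the glucosyltransferase gene UGT84A1 (0.97). The serine carboxypeptidase-like genes scpl38 (1.29) and scpl50 (0.83) were higher as well, whereas the MADS-box gene AGL71 (-0.57) and the beta-glucosidase gene BGLU45 (-0.86) were lower. Of the 17 tested members of the lists fixed beforehand only GH3.3 was called in this fit. In the 12-array fit limma called 0 of them, 1 had an unadjusted p under 0.05, and 1, GH3.3, passed when adjusted over the list alone, which had only 3 tested members.

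Shifts of whole lists were tested in the 12-array fit on 19 lists. The REM list was higher on day 7, with a median log2 of 1.27 over 5 genes (camera adjusted p = 1.9e-13, and adjusted p = 0.0118 with an estimated correlation). It was formed after REM genes were seen among the day 7 calls, so this is not independent evidence. Plastid-encoded genes, a list also formed after such genes were seen among the day 7 falls, had a median of -0.23 on day 7 (17 of 68 above 0, camera adjusted p = 1.4e-05, but adjusted p = 0.559 with an estimated correlation). In the day 7 fit 7 of them were called lower, including atpA (log2 -0.80), psaB (-0.74), ndhD (-0.69) and psbK (-0.68). On days 1 and 3 the same list was higher, at 0.35 and 0.44 (camera adjusted p = 2.1e-05 and 8.0e-15, with adjusted p = 0.882 and 0.424 with an estimated correlation). The day 1 value was 0.09 without mock replicate 2 and -0.00477 without steroid replicate 1, neither called, and the day 3 value ran from 0.03 without mock replicate 2 to 0.87 without mock replicate 1, called in each case. With the scan date as a block the 2 values were 0.56 and 0.61. Leaving out 1 array also unbalances the replicate numbers, by which these genes differed over both treatments, and within each number the steroid array had the higher plastid median on both days. Mitochondrially encoded genes were higher on day 3 (median 0.38, limma camera adjusted p = 0.000539), as were expansins and related wall enzymes (0.18, adjusted p = 0.0202), and nuclear photosynthesis genes were lower (-0.27, adjusted p = 0.0202). Each of these 3 had an adjusted p = 0.424 with an estimated correlation, and all tested probe sets together had a median of -0.115 on that day. The mitochondrial median was -0.19 without mock replicate 2, and the latter 2 calls were lost with quantile normalization, which brought the median of all probe sets to -0.00726. With the scan date as a block the 3 values were 0.46, 0.11 and -0.25, and the wall enzyme call was lost. That call was also lost without mock replicate 1 or steroid replicate 2, and the nuclear photosynthesis call without mock replicate 1 or either steroid replicate. The other lists were not called on any of the 3 days, 7 calls having been made in all, of which only that of the REM list held with an estimated correlation.

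**Figure D3:**
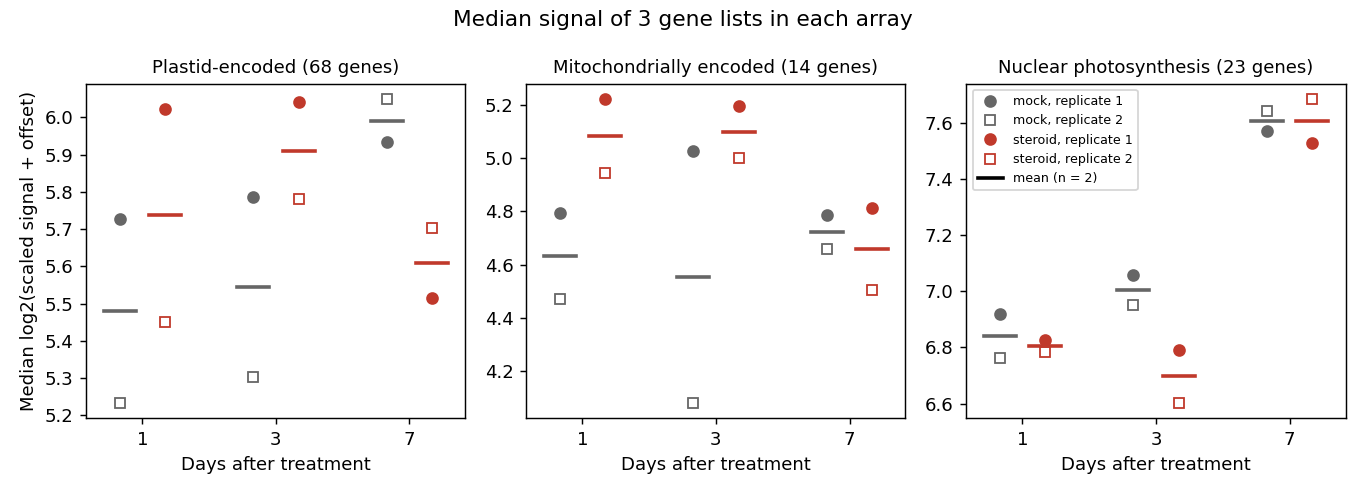
Median log2 signal per array of 68 plastid-encoded, 14 mitochondrially encoded and 23 nuclear photosynthesis genes, by day and treatment. On day 7 the plastid medians were 5.93 and 6.05 in the mock arrays and 5.52 and 5.70 in the steroid arrays, while on days 1 and 3 the plastid medians of the treatments overlapped, though within each replicate number the steroid array was higher, and the mitochondrial ones on day 1 and the nuclear ones on day 3 did not overlap.

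Averaging the 3 daily differences asked which genes differed by treatment on average, not on every day. AT3G11000 was 4.04-fold higher (log2 2.01, SE 0.13, adjusted p = 6.7e-06), AT3G19550 3.00-fold (adjusted p = 0.0109), REM22 3.59-fold (adjusted p = 0.0459) and AT1G47610 3.18-fold (adjusted p = 0.0462). The unnamed probe sets 260355_at, 251898_at, 261768_at, 254391_at, 254595_at, 246072_at and 253411_at were higher too, by log2 4.41, 3.55, 2.02, 1.84, 1.81, 1.18 and 1.12, and 246137_at was lower, by -0.84. For 254391_at and 246072_at the day 1 log2 was only 0.24 and 0.30. limma called these 12, with 1038 at an unadjusted p under 0.05 against 826 by chance. Of the 17 tested members of the lists fixed beforehand it called 0, 2 had an unadjusted p under 0.05, and 2 passed when adjusted over the list alone: ROXY1 (log2 -0.73) and TRY, a repressor of trichome formation (0.52), the only tested member of its list. Of the 19 added lists camera called 3 higher: REM (median 0.44, adjusted p = 1.2e-05), plastid-encoded (0.18, 9.8e-08) and mitochondrially encoded genes (0.22, 0.00292), with adjusted p = 0.123, 0.628 and 0.628 with an estimated correlation. The REM22 and AT1G47610 calls were each lost under 16 of 25 alternatives, with adjusted p up to 0.280 and 0.312, and that of 246137_at under 20 of 25, up to 0.316. The count was 28 without day 1 mock replicate 2 (13 higher, 15 lower), 4 without day 3 steroid replicate 2, 7 without day 7 mock replicate 1, and 6 and 5 without day 7 steroid replicates 1 and 2.

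Whether the steroid effect itself differed between days was tested directly. No gene passed: limma called 0 probe sets for day 3 against 1, 0 for day 7 against 1 and 0 for day 7 against 3, with 906, 725 and 399 at an unadjusted p under 0.05 against 826 by chance. Fits on the 8 arrays of each pair of days also called 0, with 380, 1068 and 766 at an unadjusted p under 0.05. The larger day 7 values of AT3G11000 and REM22 are therefore not shown to differ from those of days 1 and 3 gene by gene. Without 1 array the count reached at most 7, 23 and 0.

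Mock tips of day 7 and day 1 were compared for the background change with time. RCA, encoding the activase of Rubisco, was 7.96-fold higher on day 7 (50.6 ± 5.06 to 433 ± 42.3, adjusted p = 8.2e-05), and the light-harvesting gene LHCB4.1 2.16-fold. The gibberellin receptor genes GID1A and GID1B were 6.65-fold and 4.05-fold higher, and ROXY1 4.14-fold. EMS1 (log2 -0.78) and the carpel and fruit regulators ALC (-0.96) and SPT (-0.73) were lower. These 8 were the called members among the 17 tested ones of the lists fixed beforehand. Adjusted over the list alone 10 passed, as many as had an unadjusted p under 0.05. Of the 23 nuclear photosynthesis genes, 8 were higher and 4 lower (fry adjusted p = 0.0202, camera adjusted p = 0.185, and adjusted p = 0.675 with an estimated correlation), and camera called none of the 19 lists, whereas fry called 6. limma called 4169 probe sets, 2180 higher and 1989 lower, or 1987 and 2773 after centring over the tested probe sets, and 1539 or 1411 without mock day 7 replicate 1 or 2. No scan held both days, so scan and day cannot be told apart, and the GAPDH ratio above and array brightness changed with them. Without scaling, the median of all probe sets stood 2.01 higher in log2 on day 7.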

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

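The gene lists in this part were formed after the annotation and the day 7 calls had been seen, so their tests were chosen after the result was seen, as were the shares by replicate number, the ratios by day, the ratios without 1 array and the differences between lists. By camera at its preset correlation the steroid effect on 3 lists differed between days, but 0 of these differences passed with an estimated correlation or with fry. For plastid-encoded genes the median log2 effect changed by -0.52 from day 1 to day 7 and by -0.75 from day 3 to day 7 (camera adjusted p = 8.7e-10 and 1.7e-21). For mitochondrially encoded genes the changes were -0.52 and -0.44 (camera adjusted p = 0.0284 and 0.000172). For the 5 REM genes they were 1.26 and 1.11 (camera adjusted p = 0.00131 and 0.00204). With an estimated correlation the adjusted p was 0.582 and 0.358 for plastid, 0.582 and 0.417 for mitochondrial, and 0.349 and 0.358 for REM genes, and with fry the lowest was 0.127.

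Many more probe sets were called on day 7 alone (267) than on days 1 and 3 alone (0 and 0 with limma, 517 and 469 at an unadjusted p under 0.05). If only the lower noise of the day 7 arrays had made the difference, probe sets picked on one day 7 pair should change nearly as much on days 1 and 3 as in the other day 7 pair. The mean day 1 and day 3 effect of 512 such probe sets was 0.343 of the day 7 effect (0.184 on day 1, 0.502 on day 3, interval 0.247 to 0.441 over resampled probe sets, not arrays, and 0.289 to 0.396 without any 1 array of those days), below the 0.8 set beforehand. This argues against lower noise as the only difference between the days. Both day 7 pairs set scan 1 against scan 2, however, so a scan difference would enter the day 7 effect of each. Equal steroid effects on the 3 days are therefore not excluded. The scan date, which split the day 7 arrays by treatment, could be a source of the day 7 calls: 38.6% of them (27.3% of the 154 higher and 54.0% of the 113 lower) had the day 7 direction on both earlier days, and 1 of 36 relabellings of the day 1 and day 3 arrays, the real one, reached that share. The next relabelling, which parted replicate number 1 from 2 on both days, gave 37.1%. The bootstrap interval of its difference from the real share, over probe sets and not arrays, included 0 (-6.74 to 9.36 points). So did that for the highest of 15 relabellings parting no numbers (33.3%, -3.37 to 13.9 points). After quantile normalization, which took away a day 3 median shift of -0.12 over all probe sets, the real share was 45.3%, above the other 35. A requirement that the first interval lie above 0 was added after the result was seen. Scan and treatment thus cannot be told apart for these calls.

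Plastid-encoded genes were lower on day 7, with a median of -0.23 (95% bootstrap interval -0.326 to -0.101, 68 genes), a call lost with an estimated correlation (adjusted p = 0.559) and with fry (adjusted p = 0.777). Poorer priming of organelle RNA, which lacks long poly(A) tails, might lower them, but mitochondrially encoded genes had a median of -0.0639 (-0.157 to 0.0246, 14 genes), and plastid genes differed from them by -0.171 with both lists resampled (-0.306 to -0.0216, below 0 in 20 of 20 runs) but lay lower in only 3 of 4 pairs of a mock and a steroid array (-0.275 to 0.0289). Less green tissue in the steroid-treated apices might also lower them, but nuclear photosynthesis genes had a median of -0.0492 (-0.198 to 0.0227, 23 genes), and plastid genes differed from them by -0.185, and lay lower in all 4 array pairs (-0.192 to -0.158), but the resampled interval reached 0.00142 (below 0 in 2 of 20 runs). Both intervals lay above the plastid median as set beforehand, a criterion that left out the spread between arrays, which the first difference did not exceed, and that of the plastid median, which the second did not exceed, so neither explanation is excluded. A difference in plastid transcription with the steroid, and the scan of the day 7 arrays, stay open too and were not tested.

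Among 64 control probe sets, tested on 3 days in 192 tests, 3 were called, 1 higher and 2 lower. The higher one, AFFX-r2-Bs-phe-M_at, which reads a Bacillus control transcript, stood at 0.760 ± 0.232 (SD, n = 2) in mock and 13.4 ± 0.998 in steroid arrays on day 1, a log2 difference of 1.79 (adjusted p = 0.00954). Its mock signal lay below the offset of 4.35 and its steroid signal below the common median of 24.8. The lower ones were AFFX-r2-Bs-phe-3_at, which reads the same transcript (log2 -1.52, adjusted p = 0.00954), and AFFX-TrpnX-5_at (log2 -1.72, adjusted p = 0.0191), both on day 1. The 2 probe sets of 1 transcript thus went in opposite directions.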

How the results depend on the processing

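Array weights, deposited values and the shared number block were added after the data were seen. Over 65 results for named probe sets and lists and 1647 alternatives, 1349 stayed on the same side of the threshold, 224 fell short of it and 74 passed it newly. The label of reversal was given to 0. Without 1 array, however, the mitochondrial median of day 3 became -0.19 and the plastid median of day 1 -0.00477. Results not called in the main fit, many of them named from the day 7 arrays alone, counted in the 1349 when they stayed uncalled. The 1349 thus do not measure how firmly the called results held. AT3G11000, 260355_at and 251898_at on day 7 and over all days, 246072_at over all days, and the REM list on day 7 kept their calls under every alternative run. The REM list was formed after REM genes were seen among the day 7 calls of these same arrays, so its kept call is not independent support. The 3 calls of day 1 were each lost under 17 to 19 of 27 alternatives. The replicate block fixed beforehand gave 2 calls on day 1 (1 higher, 1 lower), of which 1 was shared with the main fit. On day 3 it gave 3 with 2 shared, on day 7 8 with 6 shared, and over all days 12 with 9 shared. It lost AT3G11000 and 263333_at on day 1 and 251898_at on day 3. On day 7 it lost AT5G57720, AT2G35310 and 254391_at. The day 1 count was 0 with quantile normalization, centring, no filter, no variance trend, the scan block, the 4 arrays alone or array weights, and 7 with the shared number block. Day 3 gave 1 with no filter or the scan block, and 0 with no variance trend, the 4 arrays alone or array weights. Day 7 gave 15 with the offset doubled, 5 with no variance trend, 20 with the shared number block, 267 with its 4 arrays alone, 289 with array weights and 15 with deposited values. All days gave 23 with the shared number block, 13 higher and 10 lower against 11 and 1 before, so the one-sided direction did not hold there. The day 7 against day 1 difference gave 3 with array weights and 4 with deposited values, and day 7 against day 3 gave 1 with deposited values. The mock change gave 14342 with deposited values, nearly all higher, since that setting leaves the brighter day 7 arrays unscaled. The 7 list calls became 1 with an estimated correlation and 1 with fry. The cause of the other differences was not tested. Leaving out 1 array, with the lone replicate assumed to vary like the other groups, gave 0 to 168 calls on day 1, 0 to 11 on day 3, 3 to 12 on day 7, 4 to 28 over all days, 0 to 7 for day 3 against 1, 0 to 23 for day 7 against 1, 1411 to 4823 for the mock change and 5 to 9 for the lists. The scan block could not be fitted for contrasts that include day 7. Of 22746 probe sets 16511 were bright enough to be tested, so nothing is said of the others.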

Other observations

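The tests in this part, except the splits of the arrays, were chosen after the result was seen. On days 1 and 3 the arrays numbered 1 and 2 differed in a set of genes, by a test over both treatments. The signs of RNA or cRNA quality moved with the number. The 3' to 5' GAPDH ratio was lower in number 1 in each group. On day 1 it was 4.16 against 11.2 in mock and 7.93 against 8.47 in steroid. On day 3 it was 8.36 against 12.2 and 6.60 against 15.8. In each group number 1 also had the lower actin and the higher ubiquitin ratio. In a fit of the 8 arrays with the 4 group means, limma called 192 probe sets, 100 higher and 92 lower in number 1, of which 83 had a gene name. AT4G10270 had a scaled signal of 383 ± 22.5 (SD, n = 4) in number 1 and 88.1 ± 35.7 in number 2 (log2 2.14). AT4G10260 (log2 2.29), AT3G29970 (2.25) and the plastid genes atpB (1.87), psaB (1.81) and ndhI (1.65) were higher in number 1, whereas AT3G44970 (-3.00) and the linker histone gene HIS1-3 (-2.15) were lower. Besides psaB, other genes named above for day 7 were among the 192. SWEET10 (1.42), AT5G47600 (1.02) and ndhD (0.91) were higher in number 1. BGLU45 (-1.35), SWEET11 (-1.11) and AT3G19550 (-0.76) were lower. A number difference on day 7 was not tested. Plastid-encoded genes had a median of 0.44 (61 of 68 above 0, camera adjusted p = 2.9e-12, but adjusted p = 0.288 with an estimated correlation). Expansins and related wall enzymes had -0.25 (camera adjusted p = 0.00522, and adjusted p = 0.288 with an estimated correlation). Correlations of the number difference between groups, across probe sets, ran from 0.0996 to 0.203. Each of the 8 arrays also correlated better with an array of another group than with its own replicate. The series design calls the samples independent, so the numbers were not taken as pairs in the main fit. Whether they are pairs stays open, and the replicate block described above changed several calls.

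The 12 probe sets called over the 3 days together were set against other splits of the arrays within each day. Of 100 splits, drawn from 108 possible ones, 7 gave as many calls, the real one included, and the highest other split gave 130, so by this share chance cannot be excluded for the count. The 6 others, with 130, 80, 46, 39, 39 and 36 calls, all part replicate number 1 from number 2 on days 1 and 3, which points to a structure of the samples. They are 6 of the 12 splits run that do so. Those with 130 and 80 calls also keep the real day 7 division of mock from steroid arrays. The 87 other splits run that do not part the numbers on both days gave at most 5 calls. That count was made after the result was seen, so it shows that the share depends on the structure and does not exclude chance. With a block for replicate number shared by days 1 and 3 the real split gave 23 calls, but no other split was fitted with that block. A shared handling, harvest or growth batch is a candidate explanation, which the labels do not name and which was not tested.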
